A study of Arabidopsis thaliana with 10 samples.

How the data were processed

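RNA sequencing data of hand-dissected endosperm were analysed from a series of 10 samples, 5 of lethal and 5 of viable paternal excess. Both groups had a Ler mother and a 4N Col father, wild type in the first and nrpd1 in the second. Replicates 1 and 2 of each group were sequenced as 2 parts each and replicate 3 as a single part, and the authors gave the parts as 1 column, so 3 replicates per group were compared. Sample labels put collection at 7 days after pollination, except for 1 part of lethal replicate 1 at 8 days, while the text of the series says 6 days. RNA came from a micro-scale kit and libraries from a low-input polyA kit. The balanced group came from 5 replicates of other series, of which the authors' pooled values alone were used, so it differs from the other groups in series, library batch and ploidy at once. The 10 columns of allele reads of single balanced replicates were not used here.

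The authors' notes name Trim Galore, FastQC, TopHat, Bowtie and Cuffdiff and the TAIR10 genome, and their versions, roles and settings are not given in the sources used here. The deposited allele tables hold counts of reads assigned to the Ler (maternal) or Col (paternal) allele of each gene in each replicate, and the rule of assignment is not given in the sources used here. For the balanced group the authors deposited counts and the percent of Col reads per gene from the summed reads of 5 replicates, and the percentage equals the Col share of those counts. The deposited gene expression tables hold 1 FPKM value per group and comparison, as Cuffdiff estimates it, scaled separately in each table. Balanced values printed in the text come from the comparisons with balanced, lethal and viable FPKM beside them from the same comparisons, and FPKM of the direct comparison from its own table. Per the file headers these tables also hold the test statistic of Cuffdiff, a score, and the p-value and q-value of each gene, which the authors set to 1 where no test was made. The deposited transposable element tables hold read counts per family summed over the replicates of a group, log2 ratios before and after the authors subtracted a constant per table (-1.86, -1.60 and 0.25), and a p-value and q-value. The test and annotation behind the transposable element tables are not given in the sources used here, the read total was 56256 in balanced, 196321 in lethal and 183539 in viable endosperm, and unmapped reads were left out. Signs were turned so that positive means higher in paternal excess than balanced, or higher in viable than lethal endosperm. Cells holding a spreadsheet error in place of a fold change were replaced by the ratio of the FPKM values.

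The expression tables hold 37328 genes and the allele tables another set of 37336, and 37043 of the former matched the 38094 genes of the reference table, which gave symbols only. Gene reads per library are given in the report, and reads outside genes made up 7.25% to 9.66% of the assigned reads per library. A gene with no read lay below the level of 3 reads (upper 95% limit), and library shares have Wilson and pooled gene shares Clopper-Pearson 95% intervals. Read counts varied more between replicates than counting error (variance over its expectation 15.4 to 132 within groups), so tests between groups rest on the spread between libraries where these were given singly. Tables listing a group at 0 were checked against the allele reads: 4 genes listed at 0 in balanced, 9 in lethal and 6 in viable endosperm had at least 10 CPM in that group, and none of them had been tested. One of these is AT3G13370, listed at 0 in lethal endosperm.

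Groups, comparisons, tests, alternatives and 16 gene lists (230 genes) were chosen before the data were examined. Viable and lethal endosperm were compared by edgeR 4.0.16 quasi-likelihood F tests (R 4.3.3) on Ler plus Col counts, with TMM scaling, filterByExpr and no block, so genes without allele-distinguishing reads, KNOLLE among them, could not be tested there. Alternatives were the replicate number as a block, DESeq2 1.42.0, no count filter and each library left out. Log2 differences are edgeR's with its default prior count, and CPM are TMM-scaled. A prior count of 2 was used for the log CPM behind the pairing correlations and principal components. Standard errors are the log2 difference over the root of F. Comparisons with balanced used the authors' q under 0.05. Replicate numbers were taken to pair the samples if deviations from the group mean correlated above 0.1 between equal numbers, and over 12674 genes they did (0.114, 0.475 and 0.432), the first only just, since lethal replicate 2 with viable replicate 1 gave 0.155. In percent paternal the same correlations were 0.0256, 0.0369 and 0.0366.

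Calls per list were compared with all other tested genes by one-sided Fisher's exact tests in each direction, adjusted over 96 tests, and log2 changes of lists used FPKM plus 1. Lists were also ranked by camera (limma 3.58.1) on the 6 libraries. Gene lists overlap in a few genes (NRPD1, PHE1, AGL92), and genes within a list are not independent. Parental contribution per gene was compared between viable and lethal endosperm by a quasi-binomial F test with limma's moderated dispersion (floor of 1, trend on read depth), and with balanced by two-sided Fisher's exact tests on pooled reads, for genes with at least 20 reads in each group. Genes named for the comparisons with balanced were the 10 largest fold changes each way with at least 10 FPKM in the higher group and no group at 0, NRPD1, and up to 4 members per list. The same rule was set for edgeR calls, and because edgeR made none, the 10 largest changes each way past 0.05 with the replicate block were named in their place, with at least 10 CPM in the higher group. For parental contribution and transposable elements the 5 largest each way were named, with at least 50 reads for parental contribution. The shared-control simulation (100 runs) took the spread from the deposited p-values, which gave a mean variance of 0.182 for viable against lethal changes. Genes of similar expression were given the same median spread. That median was taken only over genes with p above 0.05 and below a set upper limit. Differences in spread between genes of similar expression were thus left out. The deposited statistic gave a median of 0.531, above the observed 0.365. Neither matched the observed variance, so the simulated overlap depends on this choice. Slopes per library were taken over genes called against balanced in either comparison. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

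Tests were tried on simulated data with 200 changed genes. For edgeR each fit had its own simulated data. Without the block it recovered 0%, 25.4% and 71.2% of 2-, 4- and 8-fold changes, with 3 false calls among 67. With the block it recovered 13.4%, 61.2% and 93.9%, with 15 false calls among 127. The data for the block held a simulated replicate effect and the dispersions of the blocked fit. The higher recovery therefore does not show that the block is right for the real data. The parental test in its first form recovered 5.97% and 18.2% of shifts of 20 and 30 percentage points, and a trend on read depth was added after this, which gave 13.4% and 56.1%, and 0% of shifts of 10 points, with 0 false calls. The real data gave 0 calls in both forms. A list of 24 pollen genes was written after the authors' largest changes were seen and before counts per replicate were.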

Results

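Messenger RNA was sequenced from hand-dissected endosperm of Arabidopsis thaliana, the nutritive tissue of the seed, to examine how paternal genome dosage and a paternal nrpd1 mutation alter it. In both crosses of the series, flowers of a Ler mother received pollen of a 4N (tetraploid) Col father. The father was wild type in the group called lethal paternal excess and an nrpd1 mutant in the group called viable paternal excess. Each group held 5 samples from 3 replicates, since replicates 1 and 2 were sequenced in 2 parts each. Another group, called balanced, came from other series and entered only as the authors' values pooled over 5 replicates. Balanced endosperm carries 2 maternal genome copies and 1 paternal copy, and paternal-excess endosperm carries 2 of each.

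Reads in genes that could be assigned to a parental allele numbered 7983669, 7356862 and 7413482 in lethal replicates 1, 2 and 3. They numbered 5692640, 6303367 and 6683136 in viable replicates 1, 2 and 3, and 11895484 in the balanced pool. A gene without a read lay below 0.376 to 0.527 CPM (counts scaled by library size) per library, the level of 3 reads, and this floor and all intervals given cover counting error only. Replicate 3 stood apart in both groups. A read was found for 15829 genes in lethal replicate 3 and for 13465 in viable replicate 3, against 16560 to 17246 in the other 4 libraries. The 20 most abundant genes took 16.4% and 19.9% of the reads of these libraries and 9.80% to 10.3% in the other 4. Along the first principal component, with 47.1% of the variance, viable replicate 3 lay at 117 and the other 5 libraries between -59.3 and 23.9. The replicates may be technical, so p-values measure the spread between these samples.

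NRPD1 (AT1G63020, TAIR10 chromosome 1, 23354685 to 23362589), which encodes the largest subunit of RNA polymerase IV and is the gene mutated in the father of the viable group, was transcribed in all groups. The authors' deposited table gave NRPD1 2.33 FPKM in balanced, 6.96 in lethal and 5.71 in viable endosperm, rises of 2.99-fold (q = 0.00536) and 2.45-fold (q = 0.00877). Between the paternal-excess groups NRPD1 stood at 67.0 ± 56.7 CPM in lethal and 57.3 ± 36.5 CPM in viable libraries (SD, n = 3 each), with no call (edgeR adjusted p = 0.994). Paternal reads made up 55.2% ± 4.86 of its allele reads in lethal and 36.7% ± 8.40 in viable libraries (SD, n = 3 each), which did not pass the test (adjusted p = 0.571). In the balanced pool they made up 62.4% of 569 NRPD1 reads (95% Clopper-Pearson interval 58.3 to 66.4%).

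Lethal paternal-excess endosperm was compared with balanced endosperm to ask what a 4N wild-type father changes. The authors' deposited table gave the largest rise to AT4G32370 (chromosome 4, 15625558 to 15627517), from 0.421 to 432 FPKM (1026-fold, q = 0.00035). PHE2 (AT1G65300, chromosome 1, 24254929 to 24255857), a MADS-box transcription factor gene, rose in the authors' deposited table from 0.904 to 317 FPKM (350-fold). MPK10 (AT3G59790), a mitogen-activated protein kinase gene, went from 0.548 to 224 FPKM in the authors' deposited table (409-fold). scpl47 (AT5G22980), a serine carboxypeptidase-like gene, went from 2.5 to 864 FPKM in the authors' deposited table (345-fold). The authors' deposited table put the other 6 of the 10 largest rises, AT1G49900, AT2G12190, AT1G42980, AT5G07850, AT1G29080 and AT4G34330, between 383- and 535-fold. Storage protein genes were among the largest falls. CRA1 (AT5G44120), which encodes a cruciferin, went from 259 to 0.266 FPKM in the authors' deposited table (976-fold lower). SESA2 (AT4G27150), which encodes a seed storage albumin, went from 301 to 0.35 FPKM in the authors' deposited table (858-fold lower). The authors' deposited table had AT4G33560 fall from 585 to 0.504 FPKM (1161-fold lower) and EPR1 (AT2G27380, chromosome 2, 11713411 to 11715774), an extensin-like gene, from 1361 to 1.31 FPKM (1040-fold lower). UMAMIT23 (AT1G68170), of an amino acid transporter family, fell from 136 to 0.279 FPKM in the authors' deposited table (486-fold lower). E12A11 (AT1G18100), of the phosphatidylethanolamine-binding family, fell from 1195 to 2.61 FPKM in the authors' deposited table (459-fold lower). SESA4, AT5G55410, AT3G22540 and AT4G10265 made up the rest of the 10 largest falls, 475- to 576-fold lower in the authors' deposited table.

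Viable paternal-excess endosperm was compared with balanced endosperm to ask the same of a 4N nrpd1 father, and AT4G32370 and PHE2 were again among the largest rises. The authors' deposited table gave them 209 FPKM (494-fold, q = 0.00048) and 289 FPKM (319-fold). PHE1 (AT1G65330), an imprinted MADS-box gene, rose from 1.5 to 340 FPKM and ABCB10 (AT1G10680), an ABC transporter gene, from 0.200 to 45.0 FPKM in the authors' deposited table (both 226-fold). AT2G17305 rose 303-fold, and AT3G13370, AT3G24210, AT1G12170, AT1G29080 and AT1G42980 rose 237- to 328-fold in the authors' deposited table. For AT3G13370 the authors' deposited table listed lethal endosperm at 0 without a test, while the lethal replicates held 22003, 24626 and 36070 allele reads and the viable replicates 14220, 11212 and 33179. Among the falls, IPT6 (AT1G25410), a cytokinin synthesis gene, went from 214 to 1.16 FPKM in the authors' deposited table (184-fold lower). GLP6 (AT5G39100), a germin-like gene, fell 169-fold and EC1.3 (AT2G21750), of a family of egg cell secreted proteins, 145-fold in the authors' deposited table. In lethal endosperm the authors' deposited table put these genes at 0.0233, 0.00873 and 0.0133 FPKM but made no call (q = 0.390, 0.263 and 0.193). CRA1 and E12A11 fell 117- and 126-fold, and AT4G38410, AT2G23400, AT4G33560, AT4G30650 and AT1G12805 fell 116- to 490-fold in the authors' deposited table.

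Type I MADS-box genes, many of them active in early endosperm, rose in both groups. The authors' deposited table called 14 of 18 tested members higher and 1 lower in lethal endosperm (14 and 1 adjusted over the list alone, enrichment adjusted p = 1.60e-06). It was 12 higher and 1 lower of 16 in viable endosperm in the authors' deposited table (13 and 1 adjusted over the list alone, adjusted p = 1.60e-06). The authors' deposited table gave PHE1 429 FPKM in lethal endosperm (286-fold), and listed AGL23 at 0 in balanced, 12.1 in lethal and 7.85 FPKM in viable endosperm. AGL62 (AT5G60440), which holds back endosperm cellularisation, rose from 0.0994 to 3.66 FPKM in lethal endosperm (36.9-fold) and stood at 0.853 FPKM in viable endosperm without a call (q = 0.0544) in the authors' deposited table. Paternally expressed imprinted genes, which share PHE1 and AGL92 with the MADS-box list, rose too. The authors' deposited table called 11 higher and 2 lower of 16 in lethal (12 and 2 adjusted over the list alone, adjusted p = 0.000103) and 12 higher and 1 lower of 16 in viable endosperm (12 and 1 adjusted over the list alone, adjusted p = 1.60e-06). HDG3, a homeodomain gene, rose from 32.1 to 679 FPKM in lethal and 870 FPKM in viable endosperm in the authors' deposited table. SUVH7, a histone methyltransferase family gene, rose from 0.39 to 14.5 and 13.3 FPKM in the authors' deposited table. PEG1 went the other way, 15.6-fold lower in lethal and 2.22-fold lower in viable endosperm in the authors' deposited table. Of the maternally expressed imprinted genes the authors' deposited table called 5 higher and 0 lower of 11 in lethal (5 and 0 adjusted over the list alone, adjusted p = 0.151) and 4 higher and 0 lower of 10 in viable endosperm (5 and 0 adjusted over the list alone, adjusted p = 0.189). HDG8, another homeodomain gene, rose from 0.276 to 42.7 and 49.8 FPKM in the authors' deposited table. FWA was called in lethal (87.9 from 0.509 FPKM, q = 0.049) and not in viable endosperm (37.4 FPKM, q = 0.0666) in the authors' deposited table.

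Genes of RNA-directed DNA methylation went both ways, with 4 higher and 8 lower of 22 in lethal endosperm (4 and 10 adjusted over the list alone, adjusted p for lower = 0.117) in the authors' deposited table. The authors' deposited table called 4 higher and 4 lower of 22 in viable endosperm (4 and 7 adjusted over the list alone, adjusted p for lower = 0.880). RDR2, the RNA polymerase that acts with RNA polymerase IV, fell from 6.81 to 1.37 FPKM in lethal endosperm (4.99-fold lower), and stood at 4.04 FPKM in viable endosperm without a call (q = 0.108) in the authors' deposited table. AGO4, which binds small RNAs, fell 2.90-fold in lethal endosperm, and AGO9 rose 3.37- and 4.19-fold in lethal and viable endosperm in the authors' deposited table. Among other DNA methylation and demethylation genes the authors' deposited table called 5 higher and 1 lower of 13 in lethal (6 and 1 adjusted over the list alone, adjusted p = 0.268) and 6 higher and 1 lower of 13 in viable endosperm (6 and 1 adjusted over the list alone). The viable enrichment had adjusted p = 0.0491, and adjusted p = 0.136 when genes under 1 FPKM in both groups were left out of the background of the authors' deposited table. CMT3, a DNA methyltransferase, rose 5.39- and 4.76-fold, and ROS1, a DNA demethylase, fell 9.50- and 3.47-fold in lethal and viable endosperm in the authors' deposited table. Polycomb repressive complex 2 genes had 0 higher and 1 lower of 8 in lethal endosperm (0 and 0 adjusted over the list alone) and no call of 8 in viable endosperm (0 and 0 adjusted over the list alone) in the authors' deposited table. The 1 call was SWN, a histone methyltransferase, 2.13-fold lower (q = 0.0298) in the authors' deposited table, and the list's median (-0.10) and mean (0.12) log2 change differed in sign there.

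Seed storage and oil body genes fell in both groups, with 0 higher and 10 lower of 13 in each in the authors' deposited table (0 and 10 in lethal and 0 and 11 in viable endosperm adjusted over the list alone, adjusted p = 3.86e-05 and 4.71e-06). OLEO3, an oleosin of the oil body surface, fell from 2264 to 49.98 FPKM in lethal and 155 FPKM in viable endosperm in the authors' deposited table. SESA3, a storage albumin gene, fell from 531 to 2.33 and 12.9 FPKM in the authors' deposited table. Of the seed maturation regulators 0 were higher and 4 of 6 lower in lethal endosperm (0 and 4 adjusted over the list alone, adjusted p = 0.0592), and 0 higher and 3 of 6 lower in viable endosperm (0 and 3 adjusted over the list alone, adjusted p = 0.152), in the authors' deposited table. L1L and FUS3 encode transcription factors of seed filling. They fell from 774 to 20.8 and 69.1 FPKM and from 97.0 to 7.88 and 18.3 FPKM in the authors' deposited table. LEC1 stood at 517, 386 and 439 FPKM in balanced, lethal and viable endosperm without a call in the authors' deposited table. Photosynthesis genes fell, with 0 higher and 16 lower of 23 in lethal (0 and 19 adjusted over the list alone, adjusted p = 1.60e-06) and 0 higher and 13 lower of 23 in viable endosperm (0 and 16 adjusted over the list alone, adjusted p = 1.36e-05) in the authors' deposited table. LHCB1.2, a light-harvesting protein gene, fell from 497 to 44.5 and 117 FPKM in the authors' deposited table. PSBO2, of the oxygen-evolving complex, fell from 136 to 16.3 and 39.2 FPKM in the authors' deposited table.

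DNA replication genes had 5 higher and 0 lower of 10 in lethal (5 and 0 adjusted over the list alone, adjusted p = 0.114) and 6 higher and 0 lower of 10 in viable endosperm (8 and 0 adjusted over the list alone, adjusted p = 0.00988) in the authors' deposited table. MCM2, of the replicative helicase, rose from 11.6 to 51.9 and 52.2 FPKM in the authors' deposited table. MCM4 rose from 4.8 to 16.7 and 20.8 FPKM in the authors' deposited table. Mitotic cell cycle genes had 0 higher and 4 lower of 22 in lethal (0 and 4 adjusted over the list alone) and 1 higher and 0 lower of 22 in viable endosperm (0 and 0 adjusted over the list alone) in the authors' deposited table. KNOLLE, the syntaxin of cell plate formation, fell from 359 to 93.1 FPKM in lethal endosperm and stood at 280 FPKM in viable endosperm without a call (q = 0.633) in the authors' deposited table. CYCB1;2, the viable call, was 1.94-fold higher (q = 0.038) in the authors' deposited table. Endosperm growth and breakdown genes had 2 higher and 4 lower of 10 in lethal (3 and 4 adjusted over the list alone) and 2 higher and 2 lower of 10 in viable endosperm (2 and 3 adjusted over the list alone) in the authors' deposited table. CKX2 (AT2G19500), which breaks down cytokinin, rose from 0.873 to 62.4 and 13.8 FPKM (71.5- and 15.8-fold) in the authors' deposited table. ALE1, a subtilisin-like protease gene, fell 6.39- and 2.44-fold in the authors' deposited table. Auxin synthesis genes had no call of 7 in lethal endosperm (0 adjusted over the list alone) and YUC10 alone in viable endosperm (2.18-fold higher, q = 0.0267, 1 adjusted over the list alone) in the authors' deposited table.

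Seed coat markers, which would rise with adhering maternal tissue, had 0 higher and 4 lower of 16 in each group in the authors' deposited table (0 and 4 in each adjusted over the list alone, adjusted p for lower = 0.785 and 0.468). F3H, of flavonoid synthesis, fell from 53.5 to 5.15 and 9.02 FPKM in the authors' deposited table. TT10, a laccase gene, stood at 54.9, 78.9 and 55.4 FPKM without a call in the authors' deposited table. In lethal endosperm the list's median (0.28) and mean (-0.25) log2 change differed in sign in the authors' deposited table. Embryo markers had 7 higher and 2 lower of 16 in lethal (7 and 2 adjusted over the list alone, adjusted p = 0.0842) and 2 higher and 4 lower of 15 in viable endosperm (4 and 4 adjusted over the list alone) in the authors' deposited table. ATML1, an epidermal homeodomain gene, rose from 2.63 to 63.2 and 23.7 FPKM in the authors' deposited table. CUC1, a boundary transcription factor gene, fell from 32.4 to 0.702 and 6.07 FPKM in the authors' deposited table. Defence genes had 1 higher and 0 lower of 4 in each group in the authors' deposited table (2 and 0 in lethal and 1 and 0 in viable endosperm adjusted over the list alone), the call being PAD3, a camalexin synthesis gene listed at 0 in balanced endosperm.

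**Figure D1:**
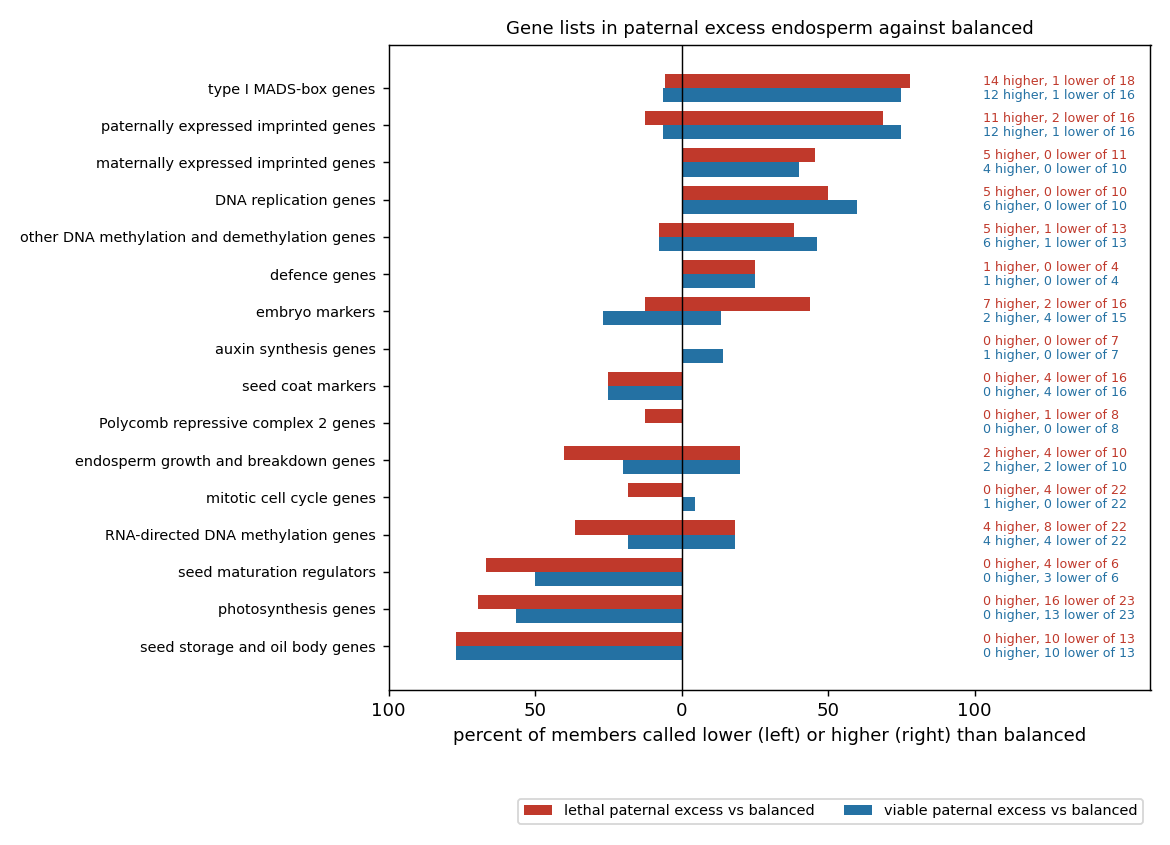
Percent of the tested members of each gene list that the authors' deposited table called lower (bars left of 0) or higher (bars right of 0) than balanced, for lethal (red) and viable (blue) paternal excess, with the counts at the right. Type I MADS-box genes had 14 of 18 and 12 of 16 members higher, and seed storage and oil body genes 10 of 13 lower in both.

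The authors' deposited table called 8042 of 23552 tested genes in lethal against balanced endosperm (4124 higher and 3918 lower, 558 of them listed at 0 in one group). It called 6240 of 23073 in viable against balanced endosperm (3267 higher and 2973 lower, 346 listed at 0 in one group), and all these calls rest on the two-sided Cuffdiff test in the authors' deposited table. Because the balanced libraries came from other series, paternal dosage cannot be told apart from series and library batch in these calls, and the spread between balanced replicates was not analysed here.

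Genes moved together in both comparisons with balanced endosperm. Of 22695 genes tested in both, 2945 were higher in both by the authors' deposited table. This was 74.9% of the 3931 lethal and 91.6% of the 3214 viable calls of the authors' deposited table. Independent lists would share 557 (Fisher's exact test, two-sided, odds ratio 205). A further 2604 were lower in both (66.6% of 3907 and 87.6% of 2973 calls, 512 for independent lists, odds ratio 99.8) and 8 were called in opposite directions in the authors' deposited table. Both comparisons used the same balanced values, which adds overlap without any effect. A simulation with a shared control and no effect gave a correlation across 15837 genes of 0.544 (observed 0.938). It gave 165 shared genes at p under 0.05 (observed 5505). The simulation gave genes of similar expression the same spread, and its overlap depends on that choice. Genes are also not independent replicates.

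SWEET11, OLEO3, SESA3 and LHCB1.2 lay between the balanced and lethal levels in viable endosperm, and most genes called in lethal endosperm changed less there. Of 7461 such genes, 81.1% had a smaller change of the same sign in viable endosperm, with a median ratio of 0.793 (0.857 for genes higher and 0.723 for genes lower in lethal endosperm), by the authors' deposited table. Selection on the lethal comparison favours this result, and among 5882 genes chosen on the viable comparison instead the share was 70.1% (median ratio 0.886) by the authors' deposited table. Per library, the slope of the change from balanced over 4374 genes was 1.02, 1.15 and 0.973 in lethal replicates 1, 2 and 3 (1.05 ± 0.0933, SD, n = 3). It was 0.836, 0.904 and 0.776 in viable replicates 1, 2 and 3 (0.839 ± 0.0643, SD, n = 3). The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. Both the genes and the mean change used for the slopes came from these same libraries, so the slopes are not an independent check.

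**Figure D2:**
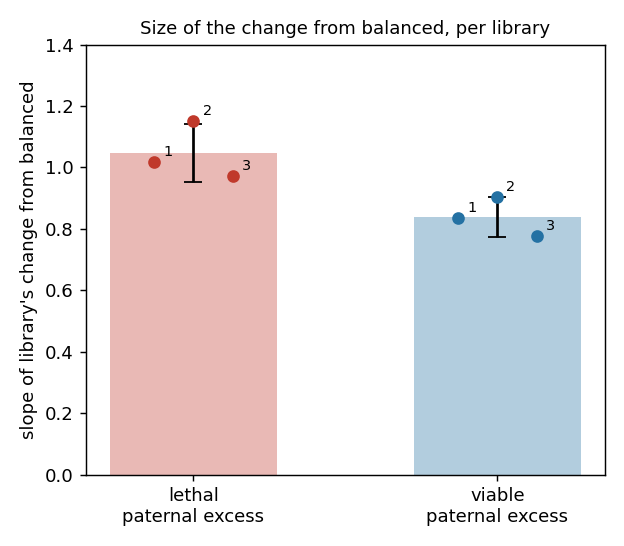
Slope of each library's log2 change from balanced against the mean change of both paternal-excess groups over 4374 genes (points, numbered by replicate), with the group mean (bar) and SD (line). All 3 viable libraries (0.776 to 0.904) lay below all 3 lethal libraries (0.973 to 1.15).

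Viable was compared with lethal paternal-excess endosperm to ask what the paternal nrpd1 mutation changes at equal ploidy. SWEET11 (AT3G48740), a sucrose transporter gene, stood at 249 ± 64.1 CPM in viable and 11.3 ± 12.9 CPM in lethal libraries (SD, n = 3 each). Its edgeR log2 difference was 4.46 (SE 0.81, adjusted p = 0.157), and adjusted p = 0.0379 with the replicate number as a block. CCH (AT3G56240), a copper chaperone gene, stood at 86.6 ± 73.4 and 5.23 ± 4.19 CPM (SD, n = 3 each; edgeR log2 difference 4.01, SE 0.32, adjusted p = 0.0153 with the block and 0.176 without it). GRP14, DMP2, AT1G28700, AT1G10880, AT3G44830, AT3G46810, GLR2.4 and AT4G33600 completed the 10 largest rises with the block, at log2 differences of 3.53 to 4.76. The authors' deposited table called all 10 of these genes lower in lethal than in balanced endosperm, SWEET11 going from 1160 to 5.44 FPKM and standing at 112 FPKM in viable endosperm. In the other direction AT1G66320 fell from 21.2 ± 6.97 to 0.190 ± 0.330 CPM (SD, n = 3 each; edgeR log2 difference -6.71, SE 0.79, adjusted p = 0.0283 with the block and 0.122 without it). ARF13 (AT1G34170), an auxin response factor gene, fell by 3.78 on the log2 scale and LCR82 (AT2G04425), of a family of small cysteine-rich secreted proteins, by 3.67 (adjusted p = 0.042 and 0.030 with the edgeR block). AT1G09360, AT1G35895, AT2G27936, AT1G56620, AT4G13955, AT2G02490 and AT3G27425 completed the 10 largest falls with the block, at log2 differences of -3.73 to -2.84. PEG1 (AT3G62230) was put on the list of paternally expressed imprinted genes. PEG1 stood at 43.2 ± 34.4 CPM in viable and 5.12 ± 2.22 CPM in lethal libraries (SD, n = 3 each). Its edgeR log2 difference was 2.90 (SE 0.48, adjusted p = 0.0434 with the block and 0.193 without it). CKX2 and AGL62 stood at 21.0 ± 10.1 and 1.99 ± 1.24 CPM in viable and at 102 ± 56.5 and 9.17 ± 0.654 CPM in lethal libraries (SD, n = 3 each) and were not called with the block (edgeR adjusted p = 0.102 and 0.174). Without the block edgeR called 0 of 12674 genes (two-sided, smallest adjusted p = 0.122, 865 at unadjusted p under 0.05) and DESeq2 189. The edgeR fit with the block called 117 genes, 83 higher and 34 lower in viable endosperm, and DESeq2 with the block called 490. The blocked count was 61 without lethal replicate 2, 60 without viable replicate 1 and 26 without viable replicate 2, and it was 20 without replicate 2 and 194 without replicate 3 of both groups.

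The authors' own test of the same groups called 614 of 24437 genes, 426 higher and 188 lower in viable endosperm, in the authors' deposited table. Genes known from pollen led the rises in the authors' deposited table: BGAL11, a beta-galactosidase gene, 0.0936 to 21.3 FPKM (228-fold), PGA4, a polygalacturonase gene (126-fold), sks13 (102-fold), and VGD1, a pectin methylesterase gene of pollen tube growth (82.3-fold). Of a list of 24 pollen genes drawn up after these were seen, the authors' deposited table called 10 higher and 0 lower in viable than in lethal endosperm (12 and 0 adjusted over the list alone). Against balanced it called 0 higher and 12 lower in lethal endosperm (0 and 13 adjusted over the list alone) and 4 higher and 0 lower in viable endosperm (3 and 0 adjusted over the list alone) in the authors' deposited table. The allele reads of the 20 detected pollen genes lay mostly in viable replicate 1 (5996 reads, 1053 CPM, against at most 37.7 CPM in each of the other 5 libraries). AT3G01270, AT3G28750, AT3G07820, AT5G19580, AT1G50650 and EPR1 made up the rest of the 10 largest rises, 27.7- to 116-fold in the authors' deposited table, and EPR1 had 7, 101 and 6 reads in lethal and 1800, 363 and 876 in viable replicates 1, 2 and 3. The authors' deposited table had AT1G66320 fall from 12.5 to 0.0741 FPKM (168-fold lower), AT1G62500 fall 29.0-fold and GH9B9, a glycosyl hydrolase gene, fall 7.92-fold. Lethal replicate 2 carried the difference in GH9B9, with 52, 657 and 42 reads in lethal and 63, 3 and 11 in viable replicates 1, 2 and 3. AT1G62500 had 681, 2033 and 8 reads in lethal replicates. AT3G23955, AT4G33830, AT2G02493 (which shares its position with AT2G02490), AT3G55677, AT1G56620, AT2G04046 and AT2G25305 fell 7.38- to 15.5-fold in the authors' deposited table. Of the 614 calls, 341 were measured in edgeR on the same libraries, and 96 of these were among the 117 called with the block. Leaving out 34 genes at least 10 times higher in viable replicate 1 than in viable replicates 2 and 3 left 580 calls of the authors' deposited table. Genes with no or few allele reads could not be checked in this way, so 34 is a minimum.

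Storage, photosynthesis and mitotic genes had 3 calls each, all higher in viable than in lethal endosperm. Seed storage and oil body genes had 3 higher and 0 lower of 12 (5 and 1 adjusted over the list alone, adjusted p = 0.00988), with OLEO3 3.07-fold, SESA3 5.35-fold and SESA2 21.3-fold higher in the authors' deposited table. In the allele reads, which were too few to test SESA3 and SESA2, OLEO3 stood at 138, 96.0 and 378 CPM in viable and 75.5, 37.1 and 89.6 CPM in lethal replicates 1, 2 and 3. Over the 5 storage genes with enough allele reads the mean log2 difference was 0.97 (4 higher), and 0.21 (2 higher, median -0.03) without viable replicate 3. Mitotic cell cycle genes had 3 higher and 0 lower of 22 (5 and 0 adjusted over the list alone, adjusted p = 0.0507), these being KNOLLE (2.99-fold), CYCB2;1 (3.83-fold) and HIK, a cytokinesis kinesin gene (2.72-fold), in the authors' deposited table. Photosynthesis genes had 3 higher and 0 lower of 23 (4 and 0 adjusted over the list alone, adjusted p = 0.0531), these being LHCB1.2 (2.62-fold), LHCB1.1 (2.58-fold) and PSBO2 (2.40-fold), in the authors' deposited table. Embryo markers had CUC1 (8.48-fold) and WOX9 (3.87-fold) higher and ATML1 (2.65-fold) lower of 15 (2 higher and 3 lower adjusted over the list alone, adjusted p = 0.146) in the authors' deposited table. Single calls in the authors' deposited table were RDR2 higher (2.99-fold, q = 0.0219) of 22 RNA-directed DNA methylation genes, ROS1 higher (2.77-fold) of 13 other methylation genes, FUS3 higher (2.32-fold) of 6 maturation regulators and PEG1 higher (7.08-fold) of 16 paternally expressed imprinted genes. AGL62 was lower (4.32-fold, q = 0.0153) of 19 MADS-box genes, and ALE1 higher (2.64-fold) and CKX2 lower (4.52-fold) of 11 growth and breakdown genes, in the authors' deposited table. Adjusted over the list alone these 6 lists had 1, 1, 1 and 2 higher, 2 lower, and 1 higher with 2 lower, in that order, in the authors' deposited table. No member was called among 12 maternally expressed imprinted, 8 Polycomb repressive complex 2, 7 auxin synthesis, 10 DNA replication, 5 defence and 17 seed coat genes (0 in each adjusted over the list alone) in the authors' deposited table. The median and mean log2 change differed in sign for paternally expressed imprinted genes (-0.17 and 0.10) in the authors' deposited table.

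Ranked against all other genes by camera on the 6 libraries (two-sided, preset correlation 0.01, 15 lists), photosynthesis genes lay higher in viable endosperm (15 of 15 members, mean log2 0.76, adjusted p = 1.07e-05), as did mitotic genes (11 of 14, 0.68, adjusted p = 0.000254) and RNA-directed DNA methylation genes (15 of 19, 0.42, adjusted p = 0.0179). MADS-box genes lay lower (3 of 11 members higher, mean log2 -0.79, adjusted p = 0.0179). None of these 4 held with correlations estimated from the data (adjusted p = 0.607 with an estimated correlation for each). With the replicate block, storage genes (adjusted p = 0.0349) and maturation regulators (adjusted p = 0.0373) passed too, and all had adjusted p = 0.596 with an estimated correlation. Without lethal replicate 3, or without viable replicate 1, camera called 2 lists, photosynthesis and mitotic genes, which passed whichever library was left out, though not with correlations estimated from the data (adjusted p = 0.464 to 0.799 with an estimated correlation). Without viable replicate 2 the MADS-box list was lost too, and RNA-directed DNA methylation genes were lost without lethal replicate 1 or viable replicate 2. The mean of the RNA-directed DNA methylation genes moved to 0.18 (12 of 19 higher) without viable replicate 2, 0.26 without lethal replicate 3 and 0.72 without viable replicate 3. Other DNA methylation and demethylation genes, not called with all libraries (mean log2 0.09), passed as higher without lethal replicate 2 (0.60, adjusted p = 0.0398) and without viable replicate 3 (0.75, adjusted p = 0.0145), and turned to -0.48 without viable replicate 2. Storage genes passed as higher without lethal replicate 1 (adjusted p = 0.0174) and without viable replicate 2 (adjusted p = 0.0119). None of these held with correlations estimated from the data (adjusted p = 0.670, 0.799, 0.734 and 0.736 with an estimated correlation, in that order). Median, mean and camera direction differed in sign for paternally expressed imprinted genes (median -0.19, mean 0.04, lower) and for growth and breakdown genes (median 0.37, mean -0.02, higher), neither called.

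Parental contribution was compared to ask whether transcripts followed genome dosage. HDG3, VIM5 and YUC10, all imprinted with paternal expression, stayed mostly paternal in every group, and HDG9 and SDC, imprinted with maternal expression, stayed mostly maternal. VIM5 was 90.9% paternal in the balanced pool (95% Clopper-Pearson interval 90.1 to 91.7%), 97.2% ± 2.1 in lethal and 98.9% ± 0.194 in viable libraries (SD, n = 3 each). HDG3 was 85.7%, 86.5% ± 2.63 and 88.5% ± 0.416 paternal, and YUC10 96.4%, 99.4% ± 0.748 and 99.0% ± 0.438 in the same order. HDG9 was 1.66%, 1.18% ± 1.01 and 5.44% ± 4.8 paternal, and MYB3R2, put on the list as paternally expressed, was 1.62% ± 0.379 paternal in lethal and 10.7% ± 4.22 in viable libraries. ALN, put on the list as maternally expressed, moved from 23.6% to 53.6% ± 2.36 and 51.8% ± 0.804 (SD, n = 3 each). PEG1, put on the list as paternally expressed, was 42.1% paternal in balanced, 55.9% ± 18.6 in lethal and 53.7% ± 7.68 in viable libraries. HDG8, put on the list as maternally expressed, was 55.1% ± 2.01 paternal in lethal and 51.9% ± 3.86 in viable libraries (SD, n = 3 each). Not all listed genes thus showed the listed parental bias here. The seed coat marker TT10, of maternal tissue, was 0.352%, 0.0706% ± 0.0615 and 0.0883% ± 0.0772 paternal.

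Over 11235 genes the median was 33.8% paternal in the balanced pool, 50.2% in lethal and 50.4% in viable endosperm, where genome dosage alone would give 33.3% and 50%. Per replicate it was 50.3% ± 0.453 in lethal and 50.5% ± 0.898 in viable libraries (SD, n = 3 each), a difference of 0.218 percentage points (two-sided exact permutation p = 1, 0.1 being the smallest possible). No gene was called between viable and lethal endosperm (0 of 12688 by the two-sided quasi-binomial test with limma's variance moderation, 844 at unadjusted p under 0.05, and 0 with the replicate block). On simulated data this test recovered 13.4% of shifts of 20 and 56.1% of shifts of 30 percentage points, so differences of these sizes or smaller are not excluded. On reads pooled within groups, which compares reads and not replicates, 8221 of 11457 genes differed between lethal and balanced (7572 more paternal, 649 more maternal) and 8206 of 11525 between viable and balanced (7704 and 502; two-sided Fisher's exact test). After centring on the median shift 4045 (1713 and 2332) and 4028 (1794 and 2234) differed. In lethal endosperm the largest gains were those of AGP40, AT5G66980, AT3G46700, AT5G28010 and AT4G13180. AGP40, an arabinogalactan protein gene, went from 7.81% to 90.4% ± 9.92 (n = 2) and AT5G66980 from 2.82% to 88.2% ± 6.62 (n = 3). AT4G13180 stood at 0% (4 reads), 94.1% and 100% in lethal replicates 1, 2 and 3. AGP40 had 38, 0 and 12 reads in lethal and 210, 4 and 3 in viable replicates 1, 2 and 3. Its reads thus lay mostly in viable replicate 1, as did those of the pollen genes. Whether the source of the pollen gene reads also entered the shares of AGP40 was not tested. In viable endosperm the largest gains were those of AT2G01422, HEXO3, AT5G23100, DRIP2 and LSU2. HEXO3, a hexosaminidase gene, went from 2.54% to 75.8% ± 4.73 (n = 3) and stood at 68.2% ± 4.45 in lethal libraries. The gain of LSU2 lay in viable replicate 3 alone (88.4% of 43 reads, against 0% of 7 and 0% of 3 reads in viable replicates 1 and 2 and 7.27% in balanced). KCS19, a fatty acid elongation gene, went from 59.0% to 0.349% ± 0.415 and 1.16% ± 1.78 (n = 3 each), and TT7, of flavonoid synthesis, from 67.8% to 4.07% ± 3.55 and 12.8% ± 17.8 (n = 3 each). AT5G05020 had a lower paternal share in both groups than in balanced. FRO3 and AT2G01580 were among the largest losses in lethal endosperm, and ABCG22 and AT3G28950 in viable endosperm. FRO3 was 95.5% paternal in balanced and 58.5%, 0% and 8.33% in lethal replicates 1, 2 and 3. KCS19, AT5G05020, ABCG22 and TT7 all lie on chromosome 5 between positions 1291630 and 2563137. Because balanced came from other series, a local difference between series cannot be told apart from a loss of paternal transcripts in these genes. In none of the 15 lists with allele reads was a member called between viable and lethal endosperm, and the median over paternally expressed imprinted genes was 74.0%, 87.7% and 81.8% in balanced, lethal and viable endosperm (10 genes).

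**Figure D3:**
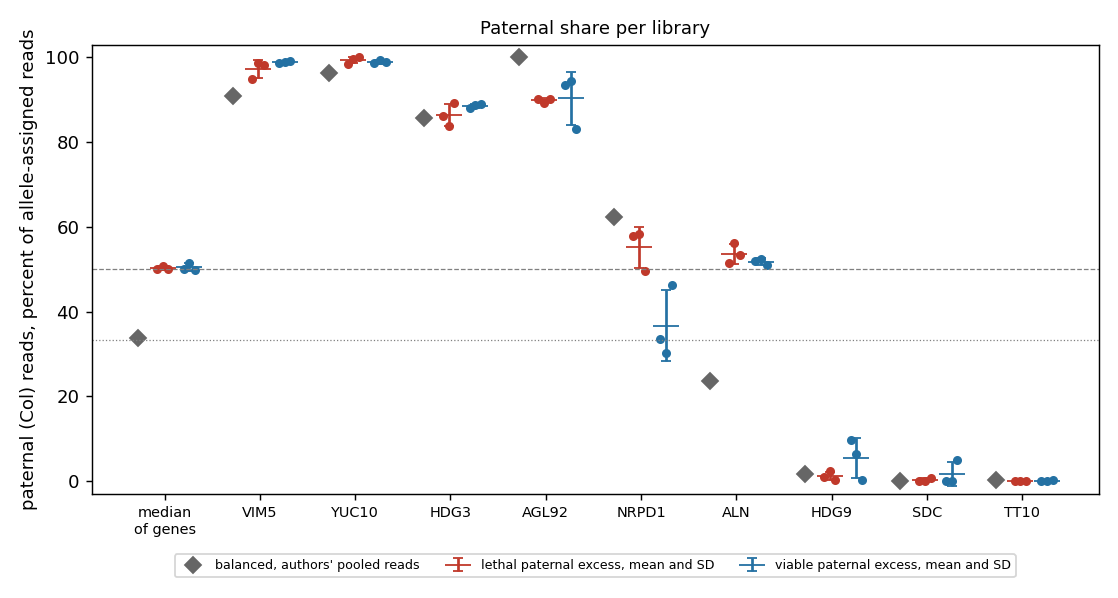
Percent of allele-assigned reads that were paternal (Col), as the median over 11235 genes and for 9 genes, in the balanced pool (diamonds) and in each lethal (red) and viable (blue) library (points, with mean and SD), dashed and dotted lines marking 50% and 33.3%. The 9 genes are examples. The median moved from 33.8% in balanced to 50.2% and 50.4%, and VIM5 and YUC10 stayed above 90% in every library.

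Transposable element families were compared by the authors on reads pooled per group. ATLINE1-10A went from 14 reads in balanced to 2928 in lethal and 2846 in viable endosperm (57.7- and 66.9-fold higher), ATGP7 from 9 to 1727 and 2213 (52.9- and 80.9-fold) and ATHAT3 from 27 to 2777 and 2714 (28.4- and 33.1-fold) in the authors' deposited table. ATCOPIA65 (46.7-fold) and ATRAN (14.1-fold) completed the 5 largest rises in lethal, and ATENSPM1 (22.6-fold) and ATCOPIA95 (21.7-fold) those in viable endosperm in the authors' deposited table. TAG1 had the largest fall, from 1062 reads to 68 in lethal and 220 in viable endosperm (56.6- and 14.7-fold lower), in the authors' deposited table. AtSB5, VANDAL2N1, ATDNA2T9A and ATHATN9 fell 8.46- to 13.9-fold in lethal endosperm in the authors' deposited table. ATCOPIA27, ATSAT5, ATHATN9 and VANDAL5A fell 4.53- to 5.72-fold in viable endosperm in the authors' deposited table. The falls of ATHATN9 rested on only 7 reads in balanced, 3 in lethal and 4 in viable endosperm in the authors' deposited table. Of 375 families the authors' deposited table called 107 higher and 51 lower in lethal, and 107 higher and 45 lower in viable endosperm, with 89 higher and 40 lower in both. ATREP helitrons had 14 higher and 1 lower of 26 in lethal and 16 higher and 1 lower in viable endosperm, and ATCOPIA elements 27 and 9, and 27 and 8, of 105 in the authors' deposited table. Between viable and lethal endosperm the authors' deposited table called 71 higher and 50 lower, of which 20 and 19 by at least 2-fold. AtSB5 (5.54-fold), ATDNA2T9A (4.31-fold), ATGP1 (4.19-fold), TAG1 (3.86-fold) and ATREP8 (3.58-fold) rose the most in the authors' deposited table. ATSINE2A (6.92-fold), ATCOPIA78 (8126 to 1472 reads, 4.63-fold), ATCOPIA14 (4.45-fold), ATTIRX1B (4.19-fold) and VANDAL1N1 (3.88-fold) fell the most in the authors' deposited table. Several of these rested on few reads in the authors' deposited table. From lethal to viable endosperm AtSB5 had 17 and 79, ATREP8 14 and 42, ATSINE2A 33 and 4, ATTIRX1B 30 and 6, and VANDAL1N1 37 and 8 reads. The median log2 change was 0.33, 0.25 and -0.06 in the 3 comparisons of the authors' deposited table. After centring on it 74 families were higher and 43 lower by at least 2-fold in lethal, against 90 and 30 before, and 75 and 36 in viable endosperm, against 81 and 27 before. Pooled reads hold no spread between replicates, so these calls do not test it.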

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

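The tests of Col pollen, male tissue, the nrpd1 mutation, sequencing depth and mixing described in this part were chosen only after the result was seen, and the others before.

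A set of 7 genes and 3 transposable elements were called in opposite directions against balanced in lethal and viable endosperm, while the authors' direct test called the difference between viable and lethal endosperm. Higher in viable endosperm were BGAL11 (log2 difference 7.83), sks12 (6.02), AT5G19580 (5.50), PHB (2.32) and AT5G18700 (2.21) in the authors' deposited table. Lower were AT1G66320 (-7.39) and AT1G62500 (-4.86) in the authors' deposited table. BGAL11, sks12 and AT5G19580 are among the pollen genes, and viable replicate 1 held 372 BGAL11 reads where the 3 lethal libraries held 0. AT5G18700 had 40, 119 and 50 reads in viable and 11, 17 and 19 in lethal replicates 1, 2 and 3. PHB, a homeodomain gene of leaf polarity, had 19.5 FPKM in balanced, 8.77 in lethal and 43.3 in viable endosperm in the authors' deposited table. AT1G66320 had 215, 188 and 87 reads in lethal and 0, 4 and 0 in viable replicates 1, 2 and 3, and AT1G62500 had 2033 of its reads in lethal replicate 2. The transposable elements ATCOPIA8A (1.67), AtSB2 (1.38) and TAG2 (1.26) were higher in viable than in lethal endosperm in the authors' deposited table.

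Most pollen genes were high in viable replicate 1 alone, with 75.0% of 20 detected markers at least 10 times higher there than in each other library, which describes the pattern and tests no explanation. RNA from Col pollen would have made their reads at least 90% paternal, and they were 37.5% paternal, which argues against Col pollen alone. An effect of the paternal nrpd1 mutation would have raised them in viable replicates 2 and 3 above every lethal library, which 0% of the detected markers showed. RNA from male tissue that is mostly maternal (Ler) in one library and a mixture of Ler and Col pollen remain open, since no value here tests them.

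Replicate 3 of both groups had fewer genes with a read. After thinning every library to 5692640 reads it still had 888 fewer genes in the lethal and 3007 fewer in the viable group than the lower of replicates 1 and 2, which argues against sequencing depth. Without the 20 most abundant genes of each library the gaps were 835 and 2978, which argues against a few genes taking most of the counts. A large loss of library complexity would have left over 5% of well expressed genes without a read. In lethal replicate 3, 0.199% of 2513 genes argue against a loss that large. In viable replicate 3, 3.42% of 3102 genes lie between the bounds of 1% and 5%. A milder loss would leave few such genes without a read, so these shares cannot decide on it. Replicate 3 was also sequenced as a single part in both groups, and replicates 1 and 2 in 2 parts each. Neither this nor a difference in stage or dissection of replicate 3, a biological explanation, was tested.

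Changes from balanced were smaller in viable than in lethal endosperm. Selection of genes on the lethal comparison would bring the share of smaller viable changes under 50% when genes are chosen on the viable comparison, and it was 70.1%. Balanced-like endosperm mixed into the viable samples would need a share of 12.4% to explain the genes lower in lethal endosperm. Percent paternal gave an estimate of -2.14%, with an upper bound of 5.10% from the replicate spread. This argues against a share of 12.4%, though with 3 libraries per group the bound is loose. For the spread between replicate libraries, the highest viable slope minus the lowest lethal slope was -0.0689, so the slopes did not overlap. The genes and the mean change behind the slopes came from these same libraries. The lack of overlap is therefore not an independent check of that spread. The paternal nrpd1 mutation, a difference in stage (1 lethal part has a label of 8 days) and an unrecorded batch were not told apart.

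Each of the 10 splits of the 6 libraries into 3 and 3 gave as many expression calls as the real grouping (10 of 10, all with 0 calls), and the same held for parental contribution (10 of 10). At unadjusted p under 0.05 the real split gave 865 genes and the highest other split 2429 for expression, and 844 and 814 for parental contribution, and so few splits cannot give a share under 0.05. Within the replicate block, which allows 4 splits, the real one gave 117 expression calls and the others at most 0.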

How the results depend on the processing

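A count was taken as the same if close in size to the main count, and a share or median if within its spread. Of 123 alternative values for main counts 93 stayed the same and 30 moved. Some of the 93 were fixed in advance, such as 0 calls under a stricter threshold. No called gene or list reversed, and the cause was not tested except where the alternative's construction (stricter threshold, fewer libraries) shows it. The block without single libraries or replicate numbers, DESeq2 with the block, camera without single libraries, with the block and with estimated correlations, and the parental test without a depth trend were chosen after the data were seen. At q under 0.01 the authors' direct calls went from 614 to 334 and shared calls from 5549 to 3694, and MPK10, AT2G02493, AT2G23400, AT2G25305 and AT4G38410 were lost. Direct edgeR calls (0, and 0 with any library left out) were 117 with the replicate block, 81 with no count filter, 189 by DESeq2 and 490 by DESeq2 with the block. The blocked count ran from 26 to 142 with 1 library left out (128, 61 and 142 without lethal replicates 1, 2 and 3, and 60, 26 and 122 without viable replicates 1, 2 and 3), and was 93, 20 and 194 without replicates 1, 2 and 3 of both groups. Apart from these and 2 camera lists (storage and maturation genes) the block changed no other call. The share of smaller changes in viable endosperm was 81.1%, 70.1% for genes chosen on the viable comparison and 76.3% for genes chosen on either. Transposable element calls between viable and lethal endosperm went from 121 to 39 with at least 2-fold change and 38 when centred on the median as well. Parental contribution calls went from 8221 to 3625 (lethal) and from 8206 to 3695 (viable) with a difference of at least 20 points, and to 4045 and 4028 when centred on the median shift. Percent paternal of summed reads was 51.6 in lethal, 51.9 in viable and 35.7 in balanced endosperm, against medians over genes of 50.2, 50.4 and 33.8. Camera lists went from 4 to 2 without lethal replicate 3, 2 without viable replicate 1, 5 without lethal replicate 2 (a range of 2 to 5 with 1 library left out), 0 with estimated correlations and 0 with both the block and estimated correlations. Lists without a camera call did change sign, embryo markers from a mean log2 difference of -0.15 to 0.56 without lethal replicate 2 and 0.64 without viable replicate 3, other methylation genes from 0.09 to -0.48 without viable replicate 2, and paternally expressed imprinted genes from 0.04 to -0.12 without viable replicate 1, among others. The median edgeR log2 difference over all genes turned from -0.05 to 0.01 with the block and without replicate 3 of both groups. The enrichment of other methylation genes in viable endosperm moved to adjusted p = 0.136 against genes with at least 1 FPKM. No paired analysis was possible against balanced, because its replicates came from other series and only their pooled values were used here, or for transposable elements, whose values were pooled. Depth limits genes under 0.376 to 0.527 CPM per library.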

Other observations

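Gene families were tested for calls after the data were seen, by Fisher's exact tests (one-sided) over all families of at least 8 genes, 1072 tests of which 14 passed. LCR genes, for small cysteine-rich secreted proteins, were higher than balanced for 33 of 59 members in lethal (adjusted p = 1.68e-08, LCR36, LCR64 and LCR59 among them) and 26 of 55 in viable endosperm (adjusted p = 1.47e-06). The same family was lower in viable than in lethal endosperm for 10 of 58 members (adjusted p = 1.68e-08, LCR61 and LCR23 among them), all by calls of the authors' deposited table. UBP genes, for ubiquitin-specific proteases, were higher than balanced for 15 of 28 members in lethal (adjusted p = 0.0029) and 14 of 28 in viable endosperm (adjusted p = 0.00153) by the authors' deposited table. IQD genes, for calmodulin-binding proteins, were lower for 18 of 29 (adjusted p = 1.31e-05) and 13 of 29 members (adjusted p = 0.00364) by the authors' deposited table. Lower as well were 8 of 13 FLA genes in lethal (adjusted p = 0.033) and 7 of 12 in viable endosperm (adjusted p = 0.0275) by the authors' deposited table. So were 13 of 28 AGP genes in lethal (adjusted p = 0.0272) and 11 of 28 HB genes in viable endosperm (adjusted p = 0.0359) by the authors' deposited table. AGP23, AGP11 and AGP40 were among these AGP genes, and the allele reads of AGP40 lay mostly in viable replicate 1, as did those of the pollen genes. MCM genes were higher in lethal endosperm for 6 of 8 members (MCM10, MCM2 and MCM6 among them, adjusted p = 0.0446) by the authors' deposited table, while the DNA replication list of the report, which holds some of them, was not enriched there (adjusted p = 0.114). SWEET sugar transporter genes were lower in lethal endosperm for 6 of 8 members (adjusted p = 0.0359, SWEET11, SWEET17 and SWEET1 among them) by the authors' deposited table. EXPA expansin genes were lower in viable than in lethal endosperm for 3 of 14 members (EXPA21, EXPA23 and EXPA25, adjusted p = 0.0205) by the authors' deposited table.

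In the balanced pool the 20 pollen genes detected in the 6 libraries had 1261 reads (106 CPM), of which 13.0% were paternal. VGDH2, a pollen gene, was called lower than balanced in lethal and higher in viable endosperm by the authors' deposited table, and their direct test did not call it (q = 0.766). SBT1.7, on the list as a seed coat gene, was 51.2% paternal in the balanced pool, 23.3% ± 4.35 in lethal and 25.0% ± 2.18 in viable libraries (SD, n = 3 each).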
